A study of Homo sapiens with 4 samples.

How the data were processed

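Total RNA of the KMS11 multiple myeloma cell line was profiled on 4 Affymetrix whole-transcript arrays, 2 from untreated cells and 2 from cells treated with EPZ025666. RNA was extracted with RNeasy and 100 ng was converted to biotinylated sense-strand DNA targets with the WT Plus reagent kit, per the labels' protocols. The deposited values are log2 signals summarised per transcript cluster or control probe set by RMA, per the submitters' processing notes, which name no version. The base of the logarithm is not stated there and was read as 2, as RMA gives log2 values. Software, library file, genome build, scan dates, treatment time and vehicle were not given in the sources used here. Array medians differ in the deposited table, so its columns were not quantile-equal. The compound is named here only by the code in the labels.

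The table held 70523 features on each array. The platform annotation listed 25324 of them with genes. Of these, 23781 carried 1 gene symbol and were used, and 1543 carried several and were left out of the gene tests, as were 45199 features listed with no gene. Where a gene had several probes, which was so for 479 genes, the probe with the highest mean over the 4 arrays was kept, which left 22465 genes. Current symbols and gene biotypes came from the reference table of assembly GRCh38.p14, used for names and classes only, and 20293 genes were matched by Entrez ID. Values were identical to those of another gene for 35 genes.

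Treated and untreated arrays were compared with limma 3.58.1 in R 4.3.3, with data.table version 1.17.8, by lmFit and eBayes with default settings and no covariate on the deposited log2 values. P-values were adjusted by the Benjamini-Hochberg method over all 22465 genes, and a gene was called at an adjusted p under 0.05 with no fold minimum. Moderation used a prior standard deviation of 0.0951 with 3.29 prior and 2 residual degrees of freedom. The labels do not say whether replicates were separate cultures, so every p-value measures the spread between these arrays only, which may be technical, and the number of arrays limits precision. A split of 2 against 2 arrays is too small for a count of other splits, and none was made.

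The test, the groups, the gene lists, the naming rule and the settings listed first among those tried were chosen before the data were examined. The lists were 30 pathways and complexes with 786 members, of which 691 were measured, and 5 lists of markers of other cell types. Each list of at least 5 measured genes was tested with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 30 lists, or over the 5 marker lists. Counts adjusted over the list alone apply the adjustment to the members of that list. Genes named were the 12 largest increases and the 12 largest decreases among called genes whose treated values both lay outside the range of the untreated ones, 15 genes fixed by name, and the 4 members with the smallest p of each list. Small RNA genes, unplaced loci and immunoglobulin or T cell receptor segments were counted as classes. Epithelial genes on a single treated array, MHC class II genes and bright increases were chosen after their values were seen.

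On simulated data with 200 changed genes among 22465, limma recovered 0 of 68 genes changed by 0.5 on the log2 scale, 63.6% of those changed by 1 and 98.5% of those changed by 2, with 2.73% false calls. With 7500 changed genes the shares were 81.7%, 98.2% and 99.8%, with 3.56% false calls. Of 5 simulated lists shifted by 0.5, camera recovered 5 with the preset and 4 with the estimated correlation, and called 0 of 25 unshifted lists with either. Simulated genes varied independently of each other and had no brightness trend. In the real lists the estimated correlation reached 0.582 and change depended on brightness, so these rates may not hold for them.

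Other settings tried were eBayes with an intensity trend and with robust hyperparameters, the replicate number as a block, quantile normalization, centring of each array on its median, 2 filters on dim genes, all features in place of genes, the mean of a gene's probes, each array left out in turn, other thresholds, and for lists the estimated correlation, fry and camera on ranks. Added after the values were seen were cyclic loess with 3 iterations, cyclic loess without EPZ025666 replicate 2, cyclic loess with the estimated correlation, and protein-coding genes alone. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.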

Results

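Gene expression was measured on 4 arrays in KMS11, an established human multiple myeloma cell line known for immunoglobulin translocations that raise FGFR3, NSD2 and MAF. In the untreated group there were 2 arrays, and another 2 came from cells treated with EPZ025666, at a concentration that the sample names give as 2.5 µM. The series title concerns PRMT5, an enzyme that symmetrically dimethylates arginine in histones, Sm proteins and other substrates, as a drug target in this cancer. The comparison of treated with untreated cells therefore asks which transcripts differ after exposure to the compound. The length of treatment and the vehicle were not given in the sources used here.

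Each array held values for 70523 features. Over the 22465 genes tested, the median log2 value was 6.19 and 6.20 on the untreated arrays and 6.35 and 6.34 on the treated ones. The interquartile range was 3.49 and 3.56 on the untreated arrays and narrower, 2.96 and 3.05, on the treated arrays. Pearson's r across genes, which are not independent replicates, was 0.998 for the untreated pair, 0.994 for the treated pair and 0.984 to 0.987 between the groups. Between the untreated replicates 3 genes differed by more than 1 on the log2 scale, and between the treated replicates 132 did. The number of arrays limits the precision of every value. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

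In treated cells the largest decrease was in GDF11, a ligand of the TGF-beta family. GDF11 fell 7.10-fold, from 10.16 ± 0.37 to 7.33 ± 0.04 (log2, SD, n = 2), a change of -2.83 with a standard error of 0.18. The MHC class II genes HLA-DQA1 and HLA-DMA fell by 2.48 and 2.05 on the log2 scale. PEG10, an imprinted gene derived from a retrotransposon, fell by 2.24, and LGI2 fell by 2.21. Next came DERL3, which acts in the degradation of misfolded proteins of the endoplasmic reticulum, at -1.98, the mucin-type glycosyltransferase gene GALNT12 at -1.97, the histone gene H2BC17 at -1.95, the antisense RNA gene VPS9D1-AS1 at -1.92, the kinase gene ALPK2 at -1.92, the ribonucleotide reductase subunit RRM2 at -1.91 and the small GTPase gene RAC3 at -1.88. Adjusted p was 0.0107 for H2BC17 and 0.00548 for the other 11 genes.

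The 12 largest increases were all in multi-copy gene families or their pseudogenes. USP17L6P, USP17L15, USP17L18, USP17L19, USP17L21 and USP17L12, copies of a deubiquitinase family, rose by 1.89, 1.68, 1.66, 1.64, 1.51 and 1.46. The olfactory receptor loci OR4F5, OR2A7, OR9A1P and OR2A4 rose by 1.85, 1.59, 1.55 and 1.53, and the exonuclease-like pseudogenes REXO1L1P and REXO1L2P by 1.81 and 1.46. Adjusted p ranged from 0.00650 for OR9A1P to 0.0273 for REXO1L2P. Values of single members of these families are uncertain, because copies can share probes, and REXO1L2P lost its call with the replicate number as a block (adjusted p = 0.0568).

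Among the 22465 genes, 4027 fell and 3846 rose at an adjusted p under 0.05, and 352 and 229 of these changed at least 2-fold. The direction depended on brightness. Median change was between 0.18 and 0.24 in the 5 dimmest deciles of genes and between -0.20 and -0.30 in the 4 brightest, on both treated arrays alike. With each array centred on its median, 6060 genes fell and 1404 rose, which put the share of increases among the calls at 18.8% in place of 48.9%, and every log2 change was lower by 0.151 than the value given here. After cyclic loess, which removes brightness-dependent differences between arrays and was added once the trend had been seen, 1753 genes fell and 1832 rose. Of these, 1563 and 1273 had the same call without it, and 0 had the opposite call. Without untreated replicate 1 or without untreated replicate 2, limma called 0 genes, with 7200 and 6383 at an unadjusted p under 0.05, while 8490 and 9630 passed without the first or the second treated replicate.

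**Figure D1:**
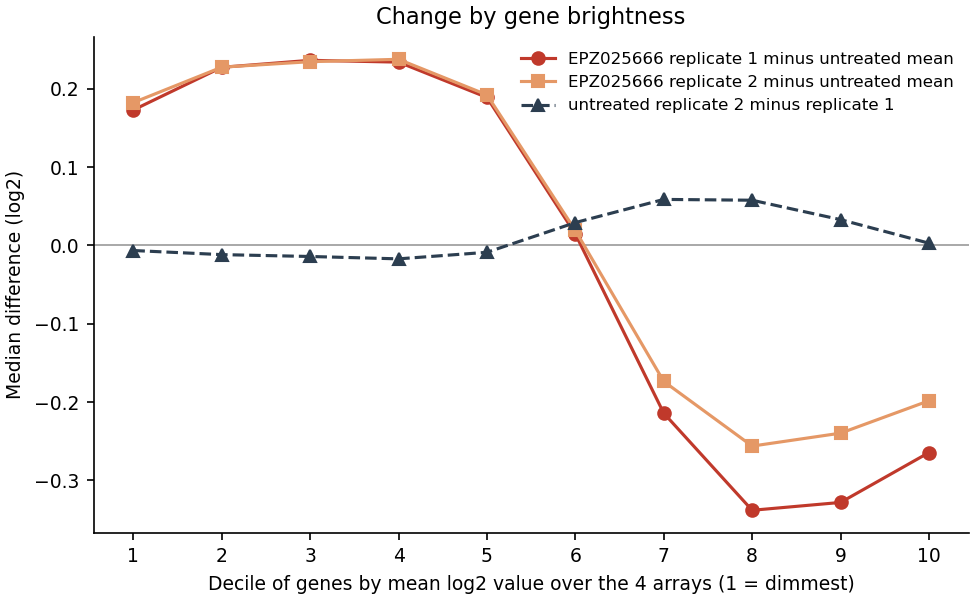
Median log2 difference between arrays, vertical axis, in deciles of genes ordered by their mean log2 value over the 4 arrays, horizontal axis, with red circles and orange squares for each EPZ025666 array against the untreated mean and dark triangles for the difference between the untreated arrays. Both treated arrays lie above 0 in the dimmest 5 deciles, by 0.17 to 0.24, and below 0 in the brightest 4, whereas the untreated arrays differ by at most 0.06 in any decile.

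PRMT5 transcript was lower in treated cells. It measured 11.67 ± 0.04 in untreated and 11.30 ± 0.08 in treated cells (log2, SD, n = 2), a change of -0.37 with a standard error of 0.08 and an adjusted p of 0.0291. This call ended with quantile normalization (-0.13, adjusted p = 0.294), after cyclic loess (-0.09, adjusted p = 0.430), after loess without EPZ025666 replicate 2 (-0.10, adjusted p = 0.448) and without either untreated replicate (adjusted p = 0.129 and 0.180). Over all 15 alternatives adjusted p ran from 0.00985 to 0.448. WDR77, the partner that PRMT5 needs for activity, fell 1.93-fold (log2 -0.94, SE 0.13, adjusted p = 0.0101). MTAP, a methionine salvage enzyme whose loss is known to raise the PRMT5-inhibiting metabolite methylthioadenosine, was expressed at 10.96 ± 0.06 in untreated cells and fell by 0.68, a call that ended after cyclic loess without EPZ025666 replicate 2 (-0.30, adjusted p = 0.0676).

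Other genes fixed by name fell as well. MYC decreased by 0.85, IRF4, a transcription factor on which myeloma cells depend, by 0.64, FGFR3 by 1.18 and NSD2, a histone methyltransferase gene, by 0.76. MAF fell by 0.63 and its target CCND2 by 0.49, and both calls ended after cyclic loess, at -0.38 and -0.29 with adjusted p of 0.0537 and 0.103, and with quantile normalization (adjusted p = 0.0613 and 0.0674). The NF-kB subunit genes NFKB1 and NFKB2 fell by 1.08 and 0.71, and NFKB2 lost its call after cyclic loess without EPZ025666 replicate 2 (-0.39, adjusted p = 0.0613). RELB was at -0.26 (adjusted p = 0.0926), TRIM21 at -0.17 (adjusted p = 0.208), the p53 regulator MDM4 at 0.06 (adjusted p = 0.533) and the cell cycle inhibitor CDKN1A at 0.27 (adjusted p = 0.0969), and none of these passed. RELB passed with arrays centred, at -0.41 (adjusted p = 0.0294), while TRIM21 turned to 0.10 with cyclic loess and MDM4 to -0.09 with centring. After cyclic loess MDM4 and CDKN1A passed as increases of 0.37 and 0.53, with adjusted p of 0.0469 and 0.0236, and CDKN1A also passed without EPZ025666 replicate 1 (adjusted p = 0.0349).

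**Figure D2:**
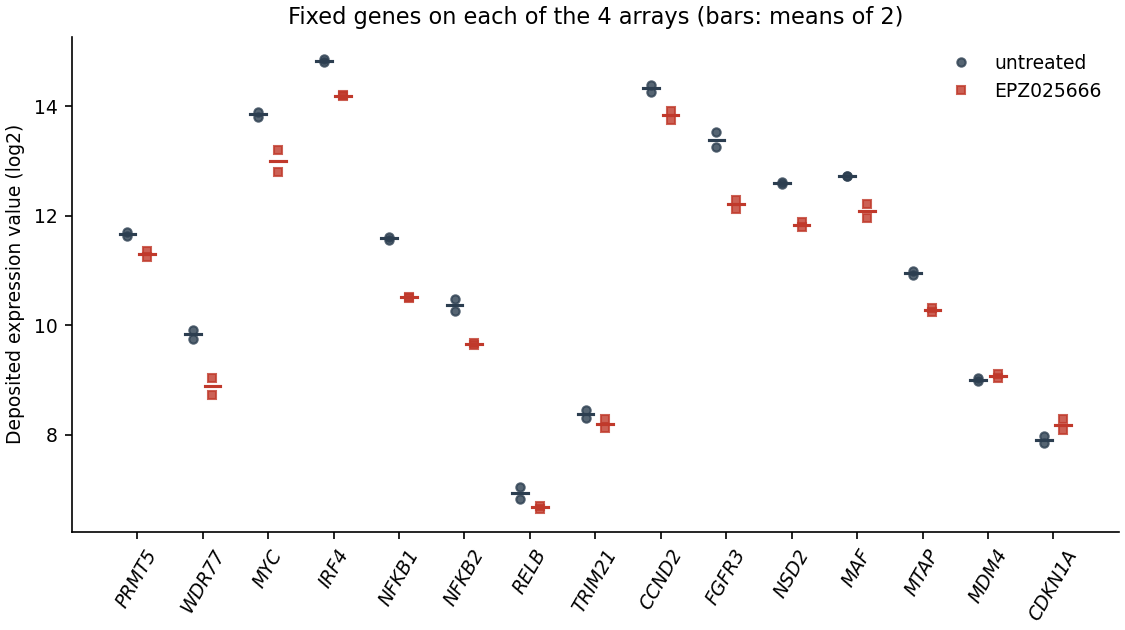
Deposited log2 value, vertical axis, of 15 genes fixed beforehand on each of the 4 arrays, with dark circles for untreated arrays, red squares for EPZ025666 arrays and bars for the means of 2. FGFR3 and NFKB1 show the widest gaps, at -1.18 and -1.08, while the groups lie close together for MDM4, at 0.06.

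Of 30 gene lists fixed beforehand, 22 shifted downward and 0 upward by limma's camera, which compares a list with all other genes under a preset correlation of 0.01. With the correlation estimated from these 4 arrays 0 lists passed, and after cyclic loess 12 passed, 10 downward and 2 upward. The estimated correlation was -0.00624 for cyclins and -0.0183 for plasma cell identity, below the preset value. Even so, their unadjusted camera p rose from 7.74e-05 to 0.0514 and from 0.00465 to 0.0902. That setting thus weakens lists whose genes are not correlated, and its outcome does not show that correlation between genes accounts for the calls. Over genes at or above the median brightness alone 10 passed, and the calls that ended there were those of DNA repair, cyclins, the methylosome, glycolysis, proteasome, lysosome, oxidative phosphorylation, SR proteins, plasma cell identity, p53, spliceosome, ribosomal proteins and NRF2. The milder filter on dim genes ended the calls of plasma cell identity, p53, spliceosome and ribosomal proteins, and protein-coding genes alone ended these and NRF2. Quantile normalization ended those that ended at or above the median brightness, except cyclins and glycolysis. By limma's fry, which tests whether a list's genes move one way, 11 of the 30 passed, and MYC and ribosome biogenesis, ATF4, histones, glycolysis, proteasome, lysosome, oxidative phosphorylation, p53, spliceosome, ribosomal proteins and NRF2 did not. For the 22 lists, the highest adjusted p among the alternatives lay between 0.524 and 0.928. Bright genes fell in general. In brightness deciles 8 to 10, each of 2246 or 2247 genes, 892 to 990 fell, at medians of -0.23 to -0.30. The medians of the methylosome, proteasome, lysosome, oxidative phosphorylation, SR protein, p53, spliceosome, ribosomal protein and NRF2 lists lay within or above this range. Their decreases thus cannot be told from the general fall of bright genes.

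DNA replication genes and other E2F targets fell most widely. Of 38 measured members 35 fell, or 38 adjusted over the list alone, and 0 rose, with a median of -0.73 (camera adjusted p = 1.06e-16, and adjusted p = 0.361 with an estimated correlation). RRM2, which supplies deoxynucleotides, fell 3.77-fold, the helicase subunit gene MCM4 2.37-fold, the replication factor gene GINS4 2.25-fold, and UHRF1, needed to maintain DNA methylation, 2.25-fold. After cyclic loess 18 members of this list were called lower, at a median of -0.45. Replication-dependent histone genes were lower too. Of 17 measured 13 fell, 13 adjusted over the list alone, with a median of -0.61 (camera adjusted p = 2.37e-05, adjusted p = 0.395 with an estimated correlation). H2AC6 fell by 0.95, H1-5 by 0.88, H1-4 by 0.73 and H2BC9 by 0.70. After cyclic loess 4 histone genes were called lower, at a median of -0.43, and H2BC9 lost its call (adjusted p = 0.0618). In the list of cyclins and CDK inhibitors 9 of 16 fell, 9 adjusted over the list alone, at a median of -0.46 (camera adjusted p = 0.000226, adjusted p = 0.361 with an estimated correlation). The members with the smallest p were the cell cycle kinases CDK4 (-0.84) and CDK2 (-0.83) and the transcription factor genes E2F4 (-0.94) and E2F3 (-0.72), none of which is a cyclin or an inhibitor. After cyclic loess 4 members were called lower, at a median of -0.24, and E2F3 lost its call (adjusted p = 0.0664).

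Several mitotic genes rose. In the G2/M list 13 of 35 genes rose and 5 fell, or 14 and 5 adjusted over the list alone. HMMR, which acts on the spindle, rose 1.94-fold (log2 0.96, SE 0.09), the checkpoint kinase gene TTK 1.78-fold, the kinetochore gene CENPF 1.66-fold and the spindle gene DLGAP5 1.64-fold. The list as a whole did not pass, with a median of 0.18 and a camera adjusted p of 0.0867. It passed as an increase after cyclic loess, where 17 members rose and 0 fell (median 0.43, adjusted p = 7.51e-08, but adjusted p = 0.578 with an estimated correlation), and under 7 other settings. Adjusted p was 2.55e-07 with quantile normalization, 0.0465 with centring, 1.13e-05 at or above the median brightness, 0.0125 with the milder filter on dim genes, 0.0171 among protein-coding genes, 0.0333 without EPZ025666 replicate 2 and 1.13e-08 after loess without that array. DNA repair genes of homologous recombination and the Fanconi pathway fell in 16 and rose in 2 of 28, 18 and 2 adjusted over the list alone, with EXO1 at -0.75, BARD1 at -0.71, FANCI at -0.85 and FANCL at -0.65. That list's median was -0.36 (camera adjusted p = 7.54e-06, adjusted p = 0.361 with an estimated correlation), and its call ended after cyclic loess, with 5 members lower and 3 higher and FANCL no longer called (list adjusted p = 0.248).

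Lipid synthesis genes fell together. In the cholesterol and SREBP list 20 of 26 fell, 21 adjusted over the list alone, and 0 rose, at a median of -0.72 (camera adjusted p = 4.41e-10, adjusted p = 0.361 with an estimated correlation). FASN, the fatty acid synthase, fell 3.27-fold, ACAT2, which makes acetoacetyl-CoA for the sterol pathway, 2.22-fold, the cholesterol carrier gene STARD4 2.15-fold, and INSIG1, a sterol-sensing regulator, 2.04-fold. After cyclic loess 13 members were called lower, at a median of -0.45. Glycolysis and hypoxia genes fell in 13 of 27, and adjusted over the list alone 13 fell and 1 rose, with HK2 at -1.32, PDK1 at -0.82, PFKP at -0.79 and PKM at -0.55. Its camera adjusted p of 0.000352 became an adjusted p = 0.395 with an estimated correlation, and 0.114 after cyclic loess, where 3 members were lower and 2 higher and PKM was no longer called.

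Genes of the secretory pathway, on which antibody-making cells rely, were lower. In the unfolded protein response list 21 of 29 fell, 23 adjusted over the list alone, and 0 rose, at a median of -0.53 (camera adjusted p = 1.20e-09, adjusted p = 0.361 with an estimated correlation). DERL3 fell 3.94-fold, the protein disulfide isomerase gene PDIA4 1.86-fold, the stress sensor gene EIF2AK3 1.83-fold and HERPUD1 1.76-fold. After cyclic loess 10 members were called lower, at a median of -0.26. Of 31 genes of the ATF4 and amino acid response 17 fell, and adjusted over the list alone 19 fell and 1 rose, at a median of -0.56 (camera adjusted p = 3.44e-07, adjusted p = 0.417 with an estimated correlation). The amino acid transporters SLC7A1 and SLC1A5 fell by 1.25 and 1.01, the serine enzyme SHMT2 by 0.72 and the stress factor DDIT3 by 0.66, and 11 members were called lower after cyclic loess, at a median of -0.39. Plasma cell identity genes were mixed, with 11 of 21 lower and 3 higher, 12 and 4 adjusted over the list alone. FKBP11, MZB1 and ELL2, which serve antibody folding and secretion, fell by 1.25, 1.21 and 0.97, while the surface enzyme CD38 rose by 0.95. The median of this list was -0.36 (camera adjusted p = 0.00775, adjusted p = 0.386 with an estimated correlation, 0.181 after cyclic loess, where 5 members were lower and 1 higher).

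Growth and arginine methylation genes fell too, the PRMT5 methylosome list at a median like that of bright genes in general. In the MYC and ribosome biogenesis list 19 of 28 fell, 23 adjusted over the list alone, at a median of -0.48 (camera adjusted p = 5.14e-08, adjusted p = 0.395 with an estimated correlation). The nucleolar genes MYBBP1A, NOLC1, UTP20 and RRS1 fell by 1.04, 0.73, 0.67 and 0.57. After cyclic loess 5 members were called lower and 1 higher, at a median of -0.27, and RRS1 lost its call, as it did with quantile normalization (adjusted p = 0.0792 and 0.0528). In the methionine and MTAP pathway 10 of 14 fell and 1 rose, the same counts adjusted over the list alone, at a median of -0.61 (camera adjusted p = 3.70e-05, adjusted p = 0.395 with an estimated correlation). The salvage enzyme ENOPH1 fell by 0.96, and the polyamine enzymes ODC1 and SRM fell by 0.88 and 0.82, and after cyclic loess 8 members were called lower and 1 higher, at a median of -0.40. Other arginine methyltransferases fell in 7 of 9, 7 adjusted over the list alone, at a median of -0.55 (camera adjusted p = 0.000507, adjusted p = 0.395 with an estimated correlation). CARM1, which places asymmetric marks, fell 2.55-fold, PRMT9 by 0.79, NDUFAF7 by 0.65 and PRMT2 by 0.55. After cyclic loess 3 of these genes were called lower, at a median of -0.30, and PRMT2 lost its call (adjusted p = 0.0576). In the PRMT5 methylosome list 7 of 13 fell, 7 adjusted over the list alone, with a median of -0.30. GEMIN5 and GEMIN4, of the complex that assembles spliceosomal particles, fell by 1.27 and 0.92, and the methylosome subunit gene CLNS1A by 0.37. This list's camera adjusted p of 0.000226 became an adjusted p = 0.386 with an estimated correlation, and 0.248 after cyclic loess. With loess its median was -0.0057, 3 members were lower and CLNS1A too lost its call at -0.08 (adjusted p = 0.525).

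Splicing genes changed in both directions. In the core spliceosome list 11 of 31 fell and 2 rose, 12 and 2 adjusted over the list alone. PRPF3, of the U4/U6 particle, rose 2.53-fold, from 12.09 ± 0.00 to 13.42 ± 0.02 (log2, SD, n = 2), and the Sm protein gene SNRPD2 rose 1.47-fold, while SNRPA and PRPF31 fell by 0.48 and 0.59. The list's median was -0.20 (camera adjusted p = 0.0119, adjusted p = 0.395 with an estimated correlation), and after cyclic loess it was 0.10 with 7 genes higher and 0 lower (adjusted p = 0.248), and SNRPA and PRPF31 were no longer called. SR protein and hnRNP genes fell in 6 of 21, 5 adjusted over the list alone, with HNRNPD, SRSF1, HNRNPL and HNRNPR at -0.49, -0.48, -0.49 and -0.37 (camera adjusted p = 0.00322, adjusted p = 0.395 with an estimated correlation). None of these 4 genes passed after cyclic loess, and HNRNPR was at -0.02 (adjusted p = 0.875) when its probes were averaged. That list's median turned from -0.18 to 0.02 with loess (adjusted p = 0.328).

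Genes of antigen presentation fell. In the MHC class I list 10 of 14 fell, 12 adjusted over the list alone, at a median of -0.53 (camera adjusted p = 7.82e-06, adjusted p = 0.397 with an estimated correlation). The immunoproteasome subunit PSMB8 fell by 0.98, the peptide transporter subunit TAP2 by 0.96, the peptidase gene ERAP1 by 0.88 and HLA-B by 0.70. After cyclic loess 4 members were called lower and 1 higher, at a median of -0.27. In the B cell program 5 of 19 fell and 2 rose, the same counts adjusted over the list alone, and the 4 with the smallest p were class II genes or their activator, CIITA at -1.59, HLA-DRB1 at -1.06, HLA-DPA1 at -0.83 and HLA-DRA at -0.79. This list did not pass (camera adjusted p = 0.673), and its median of 0.14 and mean of -0.10 differed in sign. NF-kB targets fell in 9 and rose in 3 of 30, 9 and 4 adjusted over the list alone, with CD74 at -1.41, NFKBIE at -1.21 and ICAM1 at -1.19, and after cyclic loess 7 were lower and 1 higher. This list did not pass either (median -0.10, camera adjusted p = 0.0610), except without EPZ025666 replicate 2 (adjusted p = 0.0396). Interferon response genes fell in 3 of 28, 3 adjusted over the list alone, with IFI35 at -0.91, HERC5 at -0.80 and IFIH1 at -0.39, at a median of 0.13 (camera adjusted p = 0.505), and HERC5 and IFIH1 lost their calls after cyclic loess. OAS3 was at 0.25 (adjusted p = 0.0615) and passed among protein-coding genes alone (adjusted p = 0.0427) and without EPZ025666 replicate 1 (adjusted p = 0.0459).

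Lists of stress and cell death gave mixed results. Among p53 targets 7 of 23 fell, 7 adjusted over the list alone, and 0 rose, with PMAIP1 and FAS, which promote apoptosis, at -1.03 and -0.86, TP53INP1 at -0.99 and AEN at -0.86. That list's camera adjusted p of 0.0101 became an adjusted p = 0.494 with an estimated correlation, 0.694 after cyclic loess and 0.0532 without EPZ025666 replicate 1. With loess 4 members were higher and 3 lower, and PMAIP1 lost its call, as it did with quantile normalization (adjusted p = 0.0636 and 0.0637), while FAS lost its call after loess without EPZ025666 replicate 2 (-0.48, adjusted p = 0.0551). NRF2 and oxidative stress genes fell in 5 and rose in 2 of 17, 5 and 2 adjusted over the list alone, with the pentose phosphate enzymes TALDO1 and PGD at -1.25 and -0.78, GCLM at -0.73 and AKR1C1 at 0.48. The median of -0.24 had a camera adjusted p of 0.0201 (adjusted p = 0.480 with an estimated correlation, 0.248 after cyclic loess, where 4 members were lower and 1 higher and AKR1C1 was no longer called). BCL2 family and apoptosis genes fell in 3 and rose in 1 of 20, 3 and 0 adjusted over the list alone, with BCL2 at -0.63, BID at -0.43, MCL1 at -0.38 and CASP8 at 0.36 (camera adjusted p = 0.0870), and the list passed as a decrease with centring (median -0.25, adjusted p = 0.0465). After cyclic loess 1 member was lower and 3 higher, with BID and MCL1 no longer called, and CASP8 lost its call with centring, with the block and without EPZ025666 replicate 1 (adjusted p = 0.153, 0.0710 and 0.0696). Heat shock genes rose in 3 and fell in 2 of 16, 3 and 2 adjusted over the list alone, with HSPH1 at 0.52, CHORDC1 at 0.54, DNAJB4 at 0.45 and FKBP4 at -0.48 (camera adjusted p = 0.505), and the list passed as an increase after cyclic loess (median 0.20, adjusted p = 0.0305, but adjusted p = 0.524 with an estimated correlation), where FKBP4 was no longer called. CHORDC1 lost its call with centring and with the block (adjusted p = 0.0539 and 0.0510). Immediate early genes fell in 4 and rose in 1 of 17, 4 and 1 adjusted over the list alone, with JUND at -1.68, JUNB at -0.85, JUN at -0.69 and KLF6 at -0.67 (camera adjusted p = 0.160, but 0.0333 without EPZ025666 replicate 2 and 0.0101 after cyclic loess without it), and JUNB and KLF6 lost their calls after cyclic loess. Translocation partners and MAF targets fell in 7 and rose in 3 of 17, 7 and 3 adjusted over the list alone, with ETV4 at -0.64 and the chemokine receptor gene CCR1 at 0.52 beside FGFR3 and NSD2 (camera adjusted p = 0.149).

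Lists of the proteasome, lysosome, oxidative phosphorylation and ribosome passed as decreases, but after cyclic loess none of these 4 passed and their medians lay above 0. Proteasome genes fell in 9 of 29, 9 adjusted over the list alone, with PSMD11, PSMB6, PSMC4 and PSMB4 at -0.55, -0.49, -0.46 and -0.40. The median of -0.15 (camera adjusted p = 0.000908, adjusted p = 0.429 with an estimated correlation) became 0.10 with loess (adjusted p = 0.248), with 1 member lower and 3 higher, and PSMB6, PSMC4 and PSMB4 lost their calls. Lysosome and autophagy genes fell in 8 of 27, 8 adjusted over the list alone, with BECN1, GUSB, GLA and WIPI1 at -0.76, -0.75, -0.61 and -0.42, and the median of -0.21 (camera adjusted p = 0.00145, adjusted p = 0.429 with an estimated correlation) became 0.04 (adjusted p = 0.831), with 2 lower and 2 higher and GLA and WIPI1 no longer called. Nuclear oxidative phosphorylation genes fell in 8 and rose in 1 of 28, the same counts adjusted over the list alone, with NDUFV1, NDUFB10 and UQCRC2 at -0.96, -0.60 and -0.54 and NDUFB3 at 0.58. There the median of -0.21 (camera adjusted p = 0.00145, adjusted p = 0.395 with an estimated correlation) became 0.04 (adjusted p = 0.576), with 1 lower and 1 higher and NDUFB10 and UQCRC2 no longer called. Cytosolic ribosomal protein genes fell in 2 of 22, RPS6 at -0.58 and RPS23 at -0.55, 2 adjusted over the list alone, while RPS19 at 0.26 and RPS15 at -0.26 did not pass. RPS15 passed with an intensity trend, with centring and without EPZ025666 replicate 2 (adjusted p = 0.0476, 0.0227 and 0.0278), and RPS19 under 7 settings, cyclic loess among them (adjusted p = 0.0192 to 0.0493). Their median of -0.15 (camera adjusted p = 0.0197, adjusted p = 0.553 with an estimated correlation) became 0.14 with loess (adjusted p = 0.163), with 0 lower and 1 higher, and the call ended without untreated replicate 2 (adjusted p = 0.0678) and without EPZ025666 replicate 1 (adjusted p = 0.235).

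**Figure D3:**
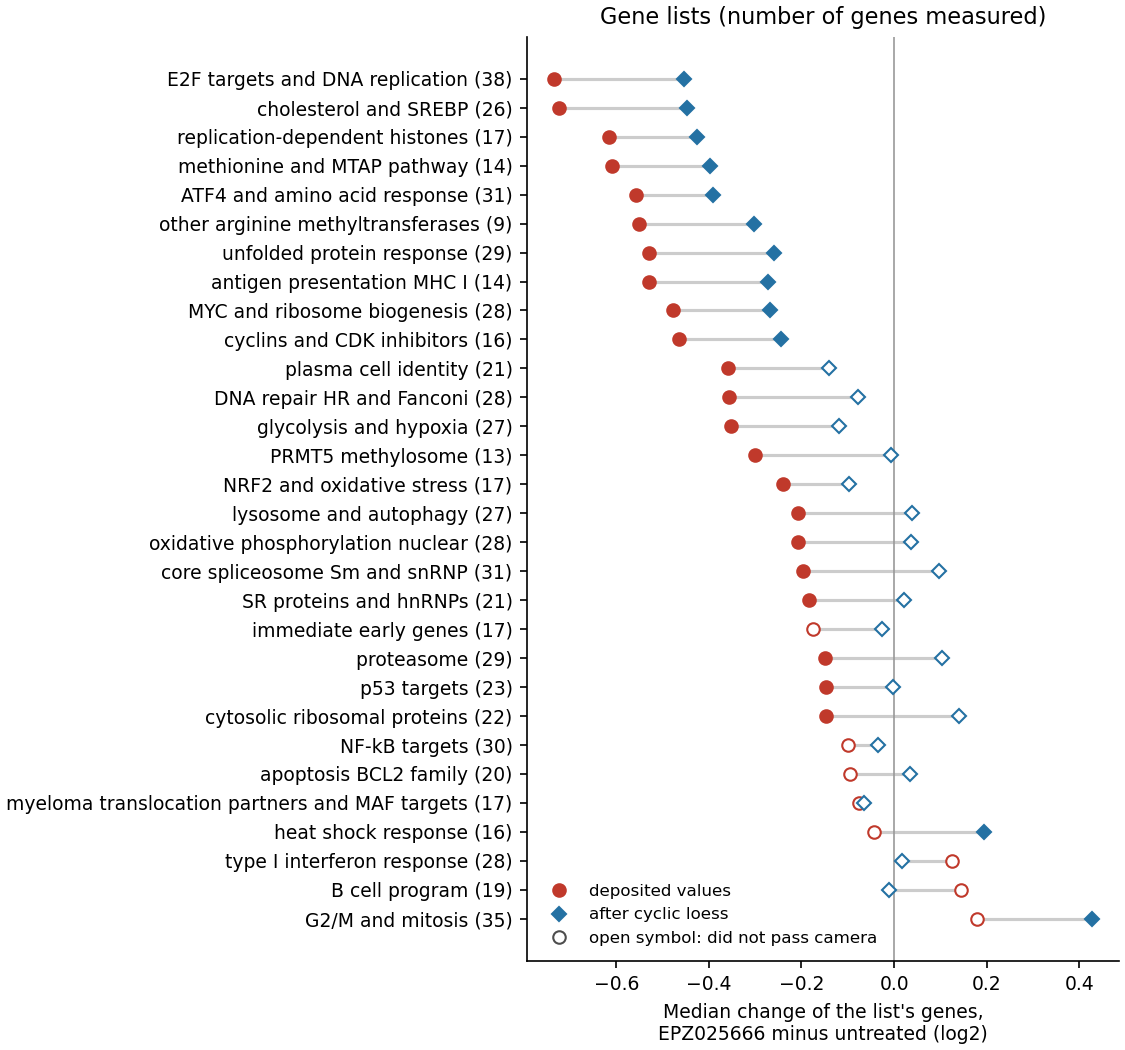
Median log2 change of each of the 30 lists, horizontal axis, with the number of genes measured beside each name on the vertical axis, red circles for the deposited values and blue diamonds after cyclic loess, and open symbols for lists that did not pass camera with the preset correlation. Medians run from -0.73 for E2F targets to 0.18 for mitotic genes, and after loess the medians of the proteasome, lysosome, oxidative phosphorylation, SR protein, spliceosome and ribosomal protein lists lie above 0.

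Small RNA genes and other loci outside messenger RNA rose in part. Of 216 small nuclear RNA genes 133 rose and 1 fell, at a median of 0.70, and after cyclic loess 112 rose and 2 fell. Of 499 genes and pseudogenes of 5S and 5.8S ribosomal RNA 218 rose and 2 fell (median 0.40), against 146 and 1 after loess (median 0.32). Of 1056 microRNA genes 290 rose and 24 fell (median 0.23), against 182 and 31 after loess (median 0.06). Of 259 small nucleolar RNA genes 67 rose and 27 fell (median 0.27), against 68 and 18 after loess (median 0.28). Immunoglobulin and T cell receptor segments rose in 68 and fell in 6 of 199 (median 0.36), against 43 and 4 after loess (median 0.21). Y, 7SL, 7SK and vault RNA genes rose in 26 and fell in 1 of 73 (median 0.40), against 17 and 1 after loess (median 0.38). LOC and LINC loci rose in 257 and fell in 21 of 760 (median 0.27), against 79 and 19 after loess (median 0.09). Among 17085 protein-coding genes 2252 rose and 3798 fell, against 1005 and 1585 after loess.

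Some markers of other cell types rose. Higher values passed for 4 of 11 epithelial, 4 of 12 myeloid, 4 of 12 T and NK cell, 4 of 13 stromal and endothelial and 2 of 8 erythroid and megakaryocyte markers, and 0 markers fell. Adjusted over the list alone the counts were 4, 4, 4, 5 and 3. Medians were 0.43, 0.24, 0.25, 0.24 and 0.25 in that order, with camera adjusted p over these 5 lists of 0.0375, 0.0329, 0.0313, 0.0313 and 0.0834, and adjusted p = 0.263 to 0.395 with an estimated correlation. These markers were dim, at untreated medians of 5.26 to 5.98. In brightness deciles 3 to 5, each of 2246 or 2247 genes, 578 to 666 genes rose, at medians of 0.20 to 0.24. Apart from the epithelial median, the counts and medians thus lie near those of dim genes in general. After cyclic loess epithelial markers alone passed (camera adjusted p = 0.0355), with 1 of 11 called higher. On the deposited values their median above untreated was 0.29 in EPZ025666 replicate 1 and 0.66 in replicate 2, so their rise lay mainly on replicate 2. Some genes, chosen after their values were seen, were high on 1 treated array only. KRT5, a keratin of basal epithelium, measured 5.94 ± 0.06 on the untreated arrays (log2, SD, n = 2), 6.23 in EPZ025666 replicate 1 and 14.38 in replicate 2 (adjusted p = 0.205), and its usual partner KRT14 measured 5.18 and 7.16 in the treated replicates (adjusted p = 0.196). Without EPZ025666 replicate 1 both passed, at 8.44 (adjusted p = 5.00e-07) and 2.09 (adjusted p = 0.000160). The next largest excesses of EPZ025666 replicate 2 over replicate 1 after KRT5 were in the metallothionein gene MT2A, in IFITM2, in the stromal marker FN1 and in the keratin gene KRT6C, at 6.04, 4.40, 3.96 and 3.72. Without replicate 1 these 4 passed at 5.49, 4.65, 3.72 and 4.12, with adjusted p of at most 1.32e-05. Without replicate 2, MT2A was at -0.55 (adjusted p = 0.00576), KRT6C at 0.39 (adjusted p = 0.0248), IFITM2 at 0.25 (adjusted p = 0.0879) and FN1 at -0.24 (adjusted p = 0.0910). Other epithelial markers were higher in replicate 2 than in replicate 1 too, KRT18 by 1.06, KRT8 by 0.86, CDH1 by 0.74, MUC1 by 0.64 and KRT7 by 0.47. EPCAM, CLDN4, ALB and KRT19 differed between the treated arrays by -0.18, -0.04, 0.02 and 0.08, and the median over the 11 markers was 0.635.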

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

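Chosen after the result was seen were the tests of background, of signal scale and of DNA or RNA outside messenger RNA for the brightness shift, and both tests on multi-copy families, while the 3 tests on EPZ025666 replicate 2 were set before their values were seen. How to read the tests on olfactory receptors, on the rise of keratinocyte markers on replicate 1 and on small RNA genes alone was also settled after their values were seen.

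Outside the gene comparison 3 signals were higher in treated arrays. Among 123 control probe sets screened, the spike-in probe set ERCC-00014 was higher by 2.71 on the log2 scale in treated arrays (11.78 and 12.33 untreated, 15.21 and 14.32 treated), and ERCC-00145 by 1.60 (7.11 and 7.87 untreated, 9.50 and 8.68 treated), whereas the median over all 92 ERCC probe sets was -0.01. The 42204 transcript clusters listed with no gene had a median change of 0.271, and 62.7% of them were higher on both treated than on both untreated arrays, where chance gives 16.7%, but they were dim, at untreated medians of 5.36 and 5.35, and genes of like brightness had medians of 0.23 to 0.24, so the value lies close to the general shift of dim genes.

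Dim genes rose and bright genes fell on both treated arrays. Higher nonspecific background is not decided, though the 23 GC-binned background bins changed by a median of -0.0224 (SD 0.177) while dim genes rose by 0.221. Single bins ran from -0.19 to 0.69, and those of 11 to 19 GC bases lay at 2.9 to 3.5, close to the array minima. Among bins about as bright as dim genes, those of 22 to 25 GC bases changed by 0.03 to 0.13 and those of 3 to 6 by -0.11 to 0.69. Bins near the minima say little about a rise, and the brighter ones scattered by more than the rise sought. A compressed signal scale is not decided. The 4 hybridisation controls added after labelling changed by a mean of 0.00971 (SD 0.139) where genes of like brightness changed by -0.268. That SD is between controls, and all 4 were higher on untreated replicate 2 than 1 and on EPZ025666 replicate 1 than 2. The control bioC, for one, read 10.10 and 10.32 untreated and 10.41 and 10.11 treated. Arrays of 1 group thus differed by amounts like the one sought. Controls added after labelling also cannot show an earlier compression. More signal from DNA or RNA outside messenger RNA in the treated preparations is not decided. The 324 olfactory receptor genes with a probe of their own were at a median of 0.373 (SD 0.308). They were taken as silent in these cells, which was not tested. They are dim genes themselves, and exceeded dim genes in general by less than the SD between genes, which is not the error of a median. A response of the cells to treatment stays open too, because the shift follows the groups in this design.

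On EPZ025666 replicate 2, 92 genes were over 1 log2 above replicate 1, with the 5 largest gaps in KRT5 (14.38 against 6.23), the metallothionein gene MT2A (12.63 against 6.59), IFITM2 (10.69 against 6.28), the stromal marker FN1 (10.33 against 6.37) and KRT6C (10.75 against 7.03), all chosen after their values were seen. The next gaps were in DSC3, CLCA2, SLPI and DSG3, at 3.39, 3.37, 3.33 and 3.28. Of the 11 epithelial markers, EPCAM, CLDN4, ALB and KRT19 differed by -0.18, -0.04, 0.02 and 0.08. Beside KRT5 and KRT14, the markers KRT18, KRT8, CDH1, MUC1 and KRT7 were higher on replicate 2, by 1.06, 0.86, 0.74, 0.64 and 0.47. The median difference of that list was 0.635. A cell line without plasma cell identity in place of KMS11 is argued against, since 21 plasma cell identity genes differed between the treated arrays by a median of -0.0299 (SD 0.197). These genes cannot tell KMS11 from another myeloma line. RNA of basal epithelial cells may be present in that preparation. The 21 basal keratinocyte markers differed by a median of 0.302 (SD 0.839), with 16 above 0. Differences were largest in DSP (2.71), SERPINB5 (2.19), CDH3 (1.92) and CSTA (1.40), and lowest in FGFBP1 (-0.30) and SERPINB13 (-0.21). KRT14, abundant in such cells, reached only 7.16 (5.18 on replicate 1). Some markers thus rose strongly and others did not, so the test leaves basal epithelial RNA open. A response to EPZ025666 is not decided either: the keratinocyte markers were at a median of 0.212 (SD 0.326) above untreated on replicate 1 against 0.473 on replicate 2, short of the bound of 0.5 of that rise set beforehand but by less than their spread. Most of these markers were dim, and all genes in brightness deciles 2 to 5 shifted by medians of 0.19 to 0.24 on replicate 1. The value of 0.212 thus cannot be told from the general shift of dim genes. The 92 genes were at a median of 0.186 (SD 0.530) on replicate 1 against 1.69 on replicate 2, with 0 reaching 0.5 of their rise, but they were picked for that gap, which holds their median on replicate 1 below 0.686 where 0.843 would be needed, so they cannot settle it.

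Multi-copy families gave the largest increases. A change in small RNA genes alone is not decided. The 63 genes of multi-copy protein-coding families, taken as silent without a test, were at a median of 0.319 (SD 0.286) after cyclic loess. The families differed, from 0.83 for DUX4L and 0.56 for POTE to 0.11 for PRAMEF and 0.02 for SPANX. Genomic DNA in the treated preparations may contribute. These families exceeded single-probe olfactory receptors, at 0.168, by 0.152. That is less than the SD of 0.286 between genes, which is not the error of a difference of medians. Neither genomic DNA nor a response to treatment is decided.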

How the results depend on the processing

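Cyclic loess, with all arrays, without EPZ025666 replicate 2 or with the estimated correlation, and the restriction to protein-coding genes were chosen after seeing the data, and all other settings were planned. The cause was not tested for the changes below, except that fewer genes or arrays enter where a setting leaves them out.

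Against 7873 genes changed, 3846 higher and 4027 lower, quantile normalization gave 3518, 1528 and 1990, cyclic loess 3585, 1832 and 1753, and a minimum of 1.5-fold 2761, 1039 and 1722. Testing all features gave 12248 calls, 8040 of them higher. Centring gave 1404 higher and 6060 lower, and genes at or above the median brightness 1168 higher. An adjusted p under 0.10 gave 6462 higher and an unadjusted p under 0.05 gave 6349. Cyclic loess without EPZ025666 replicate 2 gave 4803 calls, 2104 lower. Leaving out 1 array at a time gave 0 to 9630 genes changed, 0 to 4829 higher and 0 to 4801 lower, where the lone array is assumed to vary like the other group. The 0 came from limma without untreated replicate 1 or 2, with 7200 and 6383 genes at an unadjusted p under 0.05, against 8490 and 9630 calls without EPZ025666 replicate 1 or 2. PRMT5, at -0.37, was -0.132 with quantile normalization, -0.0929 with cyclic loess, -0.104 with loess without EPZ025666 replicate 2, its call lost in all 3, and -0.43 to -0.31 with 1 array left out, its call lost without either untreated array. Against 22 of 30 lists, 12 passed with quantile normalization, 10 at or above the median brightness, 12 with cyclic loess, 13 with loess without EPZ025666 replicate 2, 11 with fry, and 0 with the estimated correlation, alone or with loess; leaving out 1 array gave 20 to 25.

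With the replicate number as a block, 2410 genes were higher and 5597 changed. The arrays share only a number: deviations of same-numbered arrays from their group means correlated at -0.03. The block ended the calls of REXO1L2P, CLNS1A, HNRNPR, CASP8 and CHORDC1, and of no other called gene of the naming rule and no list.

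Directions turned as follows, with lists given as medians and the turn judged by camera against other genes, so that a median can keep its sign. TRIM21 was 0.10 with quantile normalization, 0.10 with loess and 0.23 with loess without EPZ025666 replicate 2, MDM4 was -0.0875 with centring, OAS3 -0.0242, KRT14 -0.123, FN1 -0.260 and MT2A -0.454 with loess without EPZ025666 replicate 2, and HLA-DQB2 -0.140 with centring. Leaving out 1 array gave -0.55 to 5.49 for MT2A, -0.24 to 3.72 for FN1, -0.0747 to 0.0969 for HLA-DQB2 and -0.0547 to 0.0155 for HLA-DOB. With quantile normalization, cyclic loess (also with the estimated correlation) and loess without EPZ025666 replicate 2, in that order, the proteasome list was at 0.0469, 0.104 and 0.110, lysosome at 0.0270, 0.0387 and 0.00732, oxidative phosphorylation at -0.0120, 0.0370 and 0.0687, SR proteins and hnRNPs at -0.0315, 0.0206 and 0.0770, spliceosome at 0.0616, 0.0967 and 0.0618, ribosomal proteins at 0.0954, 0.141 and 0.0810, the BCL2 family at 0.000169, 0.0339 and 0.0394 and heat shock at 0.139, 0.195 and 0.190. The interferon list turned to -0.0655 with loess without EPZ025666 replicate 2. At or above the median brightness spliceosome (-0.20), ribosomal proteins (-0.15), the BCL2 family (-0.10) and heat shock (-0.0443) turned, without the dimmest genes by the milder filter heat shock (-0.0443) and the B cell program (0.17), and among protein-coding genes the B cell program (0.14).

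Of 145 called genes given by the naming rule, 111 kept the call with cyclic loess, 114 with quantile normalization, 140 with the block, 143 with centring, 145 with either trend setting or without EPZ025666 replicate 2, 144 without EPZ025666 replicate 1 and 0 without either untreated array. The 31 that lost it with quantile normalization also lost it with loess, as did SRSF1, PKM and GLA. Of 11 more called genes named after their values were seen, 8 kept it with loess, 8 with quantile normalization and 0 without either untreated array. Among all of these, 0 called genes reversed. Signal over background limits what the values of dim genes can show.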

Other observations

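MHC class II genes, which present peptides to helper T cells, and bright genes that rose were chosen after their values were seen. Of 19 class II genes and their regulators 15 fell and 0 rose, at a median of -0.79. HLA-DQA1 fell 5.57-fold, HLA-DMA 4.16-fold and CIITA, the master activator of the class, 3.01-fold (log2 -1.59, SE 0.15, adjusted p = 0.00569 by limma). The invariant chain CD74 fell 2.66-fold. The regulators RFX5, RFXAP and RFXANK fell by 0.62, 0.65 and 0.53, and their calls ended with quantile normalization and after cyclic loess, where 12 genes of the list were lower and 1, HLA-DPB1, was higher. HLA-DOA, HLA-DOB, HLA-DQB2 and HLA-DPB1 did not pass, at -0.17, -0.02, 0.01 and 0.26, though HLA-DOA passed as a decrease with centring, quantile normalization and loess. HLA-DPB1 passed as an increase with quantile normalization, averaged probes, protein-coding genes alone, loess and without EPZ025666 replicate 2 (0.32, adjusted p = 0.0442), and HLA-DQB2 turned to -0.14 with centring.

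Among 6240 protein-coding genes above a log2 value of 8 in untreated cells, 198 rose and 2973 fell. Genes of the families USP17L, PPIAL, KRTAP and NBPF were then left out, and some of the largest remaining increases were picked for naming. Splicing genes PRPF3 and DDX23 rose 2.53-fold and 1.97-fold. Mitotic genes HMMR, CENPE, KIF18A and NUF2 rose by 0.96, 0.95, 0.79 and 0.78. The plasma cell surface enzyme CD38 rose by 0.95 and the sodium channel gene SCN9A also by 0.95. ATF7IP2, ANKRD12 and RICTOR, a subunit of the mTORC2 kinase, rose by 0.99, 0.91 and 0.82. All of these were also called as increases after cyclic loess.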
